A study of Arabidopsis thaliana with 12 samples.

How the data were processed

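Total RNA of wild-type Arabidopsis plants, Landsberg ecotype, was measured on 12 arrays, 6 of plants given water and 6 of plants given 500 µM bromoxynil, all sampled after 30 min of light that followed 12 h of darkness, per the labels. The deposited values are array intensities on a linear scale. In the deposited table the same feature has the value 100 on all 12 arrays, so the values are relative to the brightest feature. Between 3.14% and 4.57% of the intensities on an array are 0. How the authors scanned the arrays, subtracted background and combined spots is not given in the sources used here. Scanner output was not analysed here. The number of arrays limits the precision, and no measure of signal over background was used.

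Zeros were set to the lowest positive value of the same array and all values were taken as log2. By a rule set before the data were examined, arrays whose median log2 values differed by 0.1 or more were quantile-normalised. The medians of the deposited values, in log2, spanned 0.56, so quantile normalisation was used, and every log2 change is relative to a distribution made equal on all arrays. On the deposited log2 scale the median of the bromoxynil arrays was higher by 0.46. Each probe was tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, over all 12 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. The groups and tests, the gene lists, the rule for named genes and the alternatives of normalisation, pseudocount, dim filter, variance model, replicate block, averaged consecutive numbers and arrays left out were chosen before the data were examined.

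Probe names came from the platform annotation in GEO. Of the 692 probes with 1 gene, 690 were matched to 689 loci through gene identifiers in a table of the TAIR10.1 assembly, which was used for names only. No gene was named from a probe with several. Named genes were the 10 with the largest rise and the 10 with the largest fall among probes past the threshold that name 1 gene and lie above the dimmest 25% of probes, and up to 3 members with the smallest p of each fixed list with at least 4 measured genes. All measured members of the photosynthesis and ribosomal lists are given, and NTRC, AT1G24360 and the genes outside the fixed lists were chosen after their values were seen. Lists with at least 4 measured genes were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. Per-array values were compared with exact two-sided permutation tests over all 924 assignments of 6 arrays to a group, for which the smallest possible p is 0.00216.

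The titles number the arrays of each group from 1 to 6. Same-number arrays deviated together in every pair, with correlations of 0.450 to 0.530 over probes above the dimmest 25% and 0.323 to 0.418 over all probes, above the 0.1 set as the minimum, so by the data the numbers pair the arrays. The labels do not state what a number shares. With the number as a replicate block, 2055 probes were called. Further choices were made after the data were seen. The first adjusted each array for place: the repeat of probe numbers was found as the lag, between 49 and 1151, with the highest rank autocorrelation in the difference between 2 pairs of water arrays, which holds no treatment. It was 288. The median of probes within 6 places of the same place was then subtracted, followed by the median of each of 12 columns. The second combined this with averaged consecutive numbers (1 with 2, 3 with 4 and 5 with 6) and a block, or took these pairs as a random block, whose consensus correlation was 0.602.

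The procedures were tested on simulated data of 3439 probes with the observed means and spreads, of which 200 were changed by 0.5 or 1 on the log2 scale. With independent arrays, the fit of 12 arrays recovered 34% of the changes of 0.5 and 82% of those of 1, with 4 false calls. With errors shared by consecutive arrays at the observed correlation, it made 88 false calls, against 3 with the pairs averaged, which recovered 15% of the changes of 1. With the pairs averaged and a block, 0 false calls were made and 0% of the changes of 0.5 or 1 were recovered. These simulated errors were not shared between the groups, whereas same-number arrays of the data deviated together, so this recovery need not hold for the data. On the data, averaging with the block called 1301 probes, against 1230 with averaging alone. Whether a call lost with averaging and block reflects low power was not tested. With a smooth trend over places added to the bromoxynil arrays, the fit of 12 arrays made 1128 false calls, and 20 after the place adjustment. Of 200 simulated lists of 6 unchanged genes, camera gave a p under 0.05 for 0.5%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.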

Results

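Gene expression was compared between wild-type Arabidopsis plants of the Landsberg ecotype that received water and plants that received 500 µM bromoxynil, a nitrile herbicide that blocks electron transport through photosystem II. Plants of both groups were sampled 30 min after the lights came on again, following 12 h of darkness. Each group had 6 arrays, and each array gave 1 relative intensity for each of 3439 probes. The same feature had the value 100, the highest, on all 12 arrays. The median deposited intensity was 0.467 ± 0.0202 (SD, n = 6) with water and 0.644 ± 0.0136 (SD, n = 6) with bromoxynil. A single gene was named for 692 probes, several genes for 870 probes and none for 1877 probes. The names were not checked against probe sequences, so some may be wrong, and every value given for a gene is that of the probe annotated with it. The labels do not say that the arrays came from separate plants, so p-values measure the spread between these arrays, which may be technical.

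The first comparison asked which transcripts differed between bromoxynil and water after this short exposure to light. Among named genes on quantile-normalised values, AT3G25680 rose most, by 2.97 ± 0.18 (SE, n = 6 per group) on the log2 scale, which is 7.85-fold. AT3G23940, the dihydroxyacid dehydratase of branched-chain amino acid synthesis, rose 6.64-fold (log2 2.73 ± 0.13). AT3G52960, the plastid peroxiredoxin IIE that reduces peroxides, rose 5.51-fold (log2 2.46 ± 0.24). LpxA (AT4G29540), an acyltransferase of the lipid A type, fell most on these values, with a log2 change of -2.04 ± 0.18, though AT1G03810 fell more than LpxA on the deposited values (-1.91 against -1.86) and with medians centred (-2.37 against -2.33). PRK (AT1G32060), the phosphoribulokinase of the Calvin cycle, had a log2 change of -1.62 ± 0.19.

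The other genes among the 10 largest rises were AT4G31930 (log2 2.68 ± 0.62), AT4G09040 (2.68), AT5G46390 (2.65), AT5G65490 (2.22), AT2G30100 (2.16), AT2G47680 (2.02) and AT3G06870 (2.02). The other genes among the 10 largest falls were AT1G03810 (log2 -1.86), AT4G30740 (-1.75), AT1G15140 (-1.72), AT2G04540 (-1.64), AT2G36480 (-1.60), AT1G21660 (-1.51), AT2G04700 (-1.51) and AT3G57630 (-1.51). AT2G04540 is a mitochondrial 3-ketoacyl-acyl carrier protein synthase of fatty acid synthesis. AT2G04700 is the catalytic subunit of ferredoxin-thioredoxin reductase, which passes electrons from photosystem I to thioredoxins. For each of these 20 genes, all 6 bromoxynil arrays lay on one side of all 6 water arrays. After each array's values were adjusted for the place of the probe on the array, the log2 changes were 2.48 for AT3G25680, 1.99 for AT3G23940, 1.78 for AT3G52960, -1.57 for LpxA and -1.16 for PRK, while that of AT4G31930 was 3.04, the highest of the 10 rises. With a pseudocount in place of the floor the changes of AT3G25680, AT4G31930 and AT5G65490 were 2.21, 1.98 and 1.56, and that of AT3G23940 was the highest, at 2.38. All 10 rises and all 10 falls kept their direction and stayed past the threshold after the place adjustment. They also did so when averaging of consecutive arrays and the replicate block were added to it. The place adjustment made each of these changes smaller in size except that of AT4G31930. The smallest was then that of AT1G21660, at -0.89. With averaging alone AT4G31930 did not pass.

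**Figure D1:**
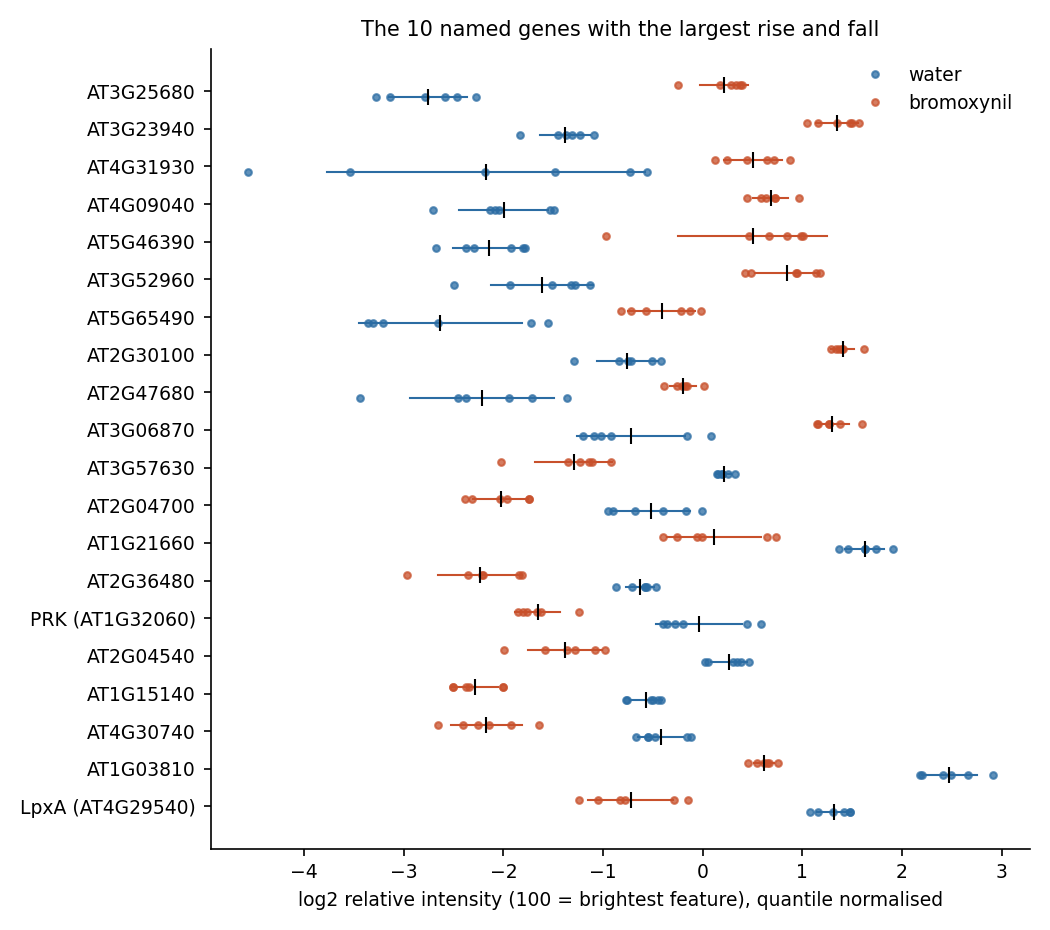
Quantile-normalised log2 relative intensity (x axis) of the 10 named genes with the largest rise and the 10 with the largest fall (y axis); each point is 1 array, the black mark is the group mean and the line is 1 SD to each side. The 6 water points and the 6 bromoxynil points of each gene do not overlap, and AT4G31930 has the widest spread, on the water arrays.

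Over all probes, 1872 of 3439 (54.4%) differed between the groups at an adjusted p under 0.05 (limma, Benjamini-Hochberg), of which 844 were higher and 1028 lower with bromoxynil. The share of higher calls was 45.1% (95% Wilson interval 42.8 to 47.3). The interval takes the called probes as independent, which they are not, so it does not measure the spread between arrays. At least a 2-fold change was seen for 790 of these probes, 399 higher and 391 lower. Among probes that name 1 gene, 178 were higher and 177 lower. The values of the groups did not overlap for 1255 probes (36.5%), against 0.216% expected by chance if all 12 arrays are independent. With consecutive arrays averaged to 3 values per group, they did not overlap for 1768 probes (51.4%), against 10% by chance. The share depended on scaling: on the values as deposited, 1301 of 1941 called probes (67.0%) were higher, and with each array centred on its median 37.7% were higher. With consecutive arrays averaged to 3 values per group, 1230 probes were called, and 956 when the place adjustment and the replicate block were added.

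Of 7 measured photosynthesis genes among the lists fixed before the data were examined, 3 fell, 1 rose and 3 did not pass the test. PRK fell as given above. LHB1B2 (AT2G34420), a chlorophyll-binding antenna protein of photosystem II, fell, with a log2 change of -0.88 ± 0.12 and an adjusted p of 8.2e-05 (limma). Its change was -1.61 with medians centred and -1.15 on the deposited values, both past the threshold. PSBY (AT1G67740), a small subunit of photosystem II, fell, with a log2 change of -0.85 ± 0.12. It was -1.01 with medians centred and -0.55 on the deposited values, also past the threshold. PSBW (AT2G30570), another photosystem II subunit, rose by 0.67 ± 0.11 on quantile-normalised values, and by 1.07 after the place adjustment, but its change was -0.21 with each array centred on its median and 0.25 on the values as deposited, neither past the threshold. The log2 changes of the others were -0.71 ± 0.47 for PSB27 (AT1G03600), 0.15 ± 0.13 for SBPASE (AT3G55800), the sedoheptulose bisphosphatase of the Calvin cycle, and -0.12 ± 0.23 for PSAN (AT5G64040), a photosystem I subunit. With medians centred PSAN passed the test, at -0.87, and on the deposited values SBPASE passed, at 0.58. With the replicate block PSB27 passed the test, with an adjusted p of 0.00851 (limma), but its log2 change was -0.17 after the place adjustment and did not pass there, with or without averaging and block. After adjustment for the place on the array, LHB1B2 and PSBY had log2 changes of -0.49 and -0.34 and no longer passed the test, whereas SBPASE passed at 0.50, but not when averaging and block were added. As a list, the 7 genes did not differ from the other genes (camera p = 0.201, limma; p = 0.217 with an estimated correlation). The rotation test fry of limma, which asks whether members move on balance in 1 direction without comparing them with other genes, gave an adjusted p of 1.43e-05, downward, and an adjusted p of 0.260 after the place adjustment.

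Plastid ribosomal proteins were the only single list with enough measured genes for a list test. Of its 6 members, 3 fell and 2 rose, and 5 were called when adjusted over the list alone. AT3G54210 (protein L17) fell, with a log2 change of -1.16 ± 0.09. AT3G13120 (S10) and AT1G64510 (S6) also fell, with log2 changes of -0.97 ± 0.14 and -0.76 ± 0.15. AT4G01310 (L5) rose by 0.63 ± 0.15 and AT1G29070 (L34) by 0.66 ± 0.23, the latter with an adjusted p of 0.0287 (limma). The probes of AT1G64510 and AT1G29070 are among the dimmest 25%. After the place adjustment the changes were -0.68 for AT3G54210, -1.42 for AT3G13120, -0.97 for AT1G64510 and 1.15 for AT4G01310, all past the threshold. AT1G29070 had a log2 change of 0.20 there and did not pass the test, nor in 7 of 12 fits that left out 1 array. AT5G65220 (L29) was listed at 0 on 5 of 6 arrays of each group, so no fold is given. As a list, these genes did not differ from the other genes (camera p = 0.317; p = 0.419 with an estimated correlation), and 0 single lists passed the threshold in limma's camera, with 0 at an unadjusted p under 0.05. For this list fry gave an adjusted p of 0.000285 (limma).

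The lists covered 444 loci, of which 21 (4.73%) were measured, and 12 of the 22 lists had no measured gene. Of the 21 genes, 5 rose, 7 fell and 9 were not called, and 12 were called when adjusted over the list alone. Besides those above, NTRC (AT2G41680), a plastid thioredoxin reductase, had a log2 change of -0.46 ± 0.12 and AT1G24360, a ketoacyl reductase of plastid fatty acid synthesis, rose by 0.39 ± 0.09. After the place adjustment, NTRC had a change of 0.02 and AT1G24360 of 0.17, and neither passed the test.

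The next comparison asked whether photosynthesis genes changed differently from genes of plastid gene expression. The median log2 change was -0.71 over the 7 photosynthesis genes and -0.16 over the 6 plastid gene expression genes, which are the ribosomal proteins above. The medians differed by -0.55, with an exact permutation p of 0.673 over all assignments of genes to the lists, a description across genes that are not independent replicates. Per array, the difference between the list medians was 1.97 ± 0.39 (SD, n = 6) with water and 1.55 ± 0.26 (SD, n = 6) with bromoxynil, with an exact two-sided permutation p of 0.0498. The exact permutation p of this per-array difference was no longer under 0.05 in 9 of 12 fits that left out 1 array. After the place adjustment the per-array difference was higher by 0.19 with bromoxynil (exact permutation p = 0.394). The difference of the median changes was -0.18 without bromoxynil array 4 and 0.16 after the place adjustment. It was 0.26 without the dimmest 25% of probes, which removes AT1G64510, AT1G29070 and AT5G65220 of the ribosomal list and no photosynthesis gene. The difference between the list medians per array was then still lower with bromoxynil (exact permutation p = 0.00216), so that p does not mark a reversal.

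Array numbers and the place of a probe both moved with the values. Arrays of the same number in the 2 groups deviated from their group means together, with a mean Pearson correlation of 0.490 (range 0.450 to 0.530) across probes above the dimmest 25%, and of 0.364 across all probes. Probes are not independent replicates. Consecutive numbers within a group were paired as 1 with 2, 3 with 4 and 5 with 6. These pairs correlated at a mean of 0.412 over probes above the dimmest 25%, and of 0.0855 (range -0.048 to 0.391) over all probes. Across the pairs, over probes above the dimmest 25%, numbers 2 and 3 correlated at -0.49 with water and -0.39 with bromoxynil. Numbers 4 and 5 correlated at -0.23 in both groups. The log2 change of the probes also followed the probe number, with a repeat every 288 numbers. Over bins of 12 places, the median change ran from -0.68 to 0.65.

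**Figure D2:**
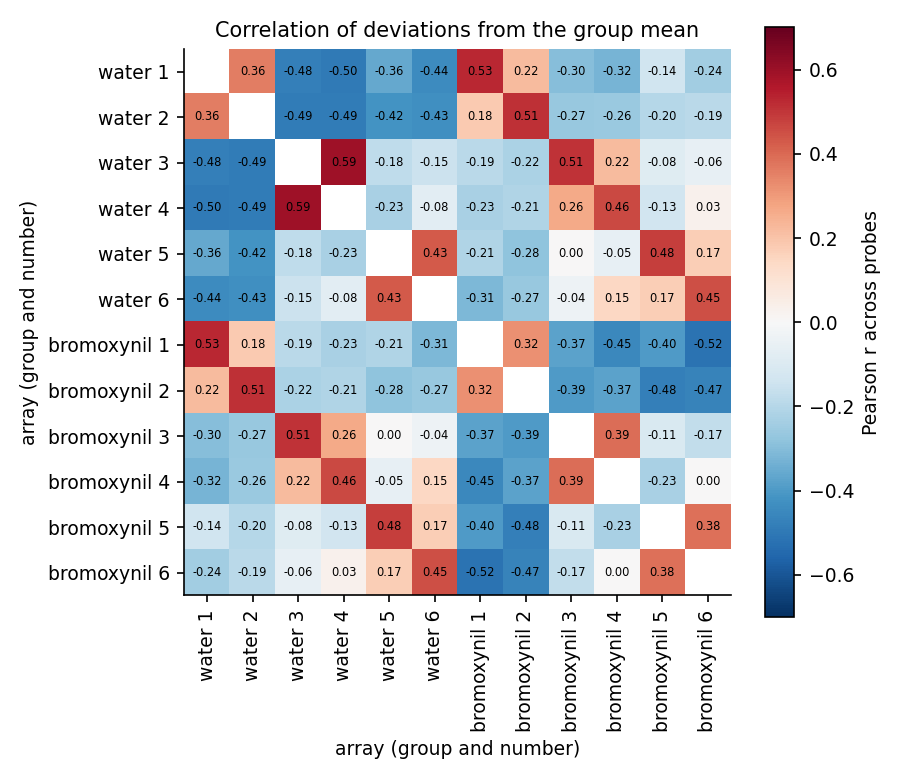
Pearson correlation across probes above the dimmest 25% (colour and printed value) between the deviations of each pair of arrays from their group means, with the 12 arrays on both axes. Same-number arrays of the 2 groups correlate at 0.450 to 0.530, above all other pairs of a water and a bromoxynil array.

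**Figure D3:**
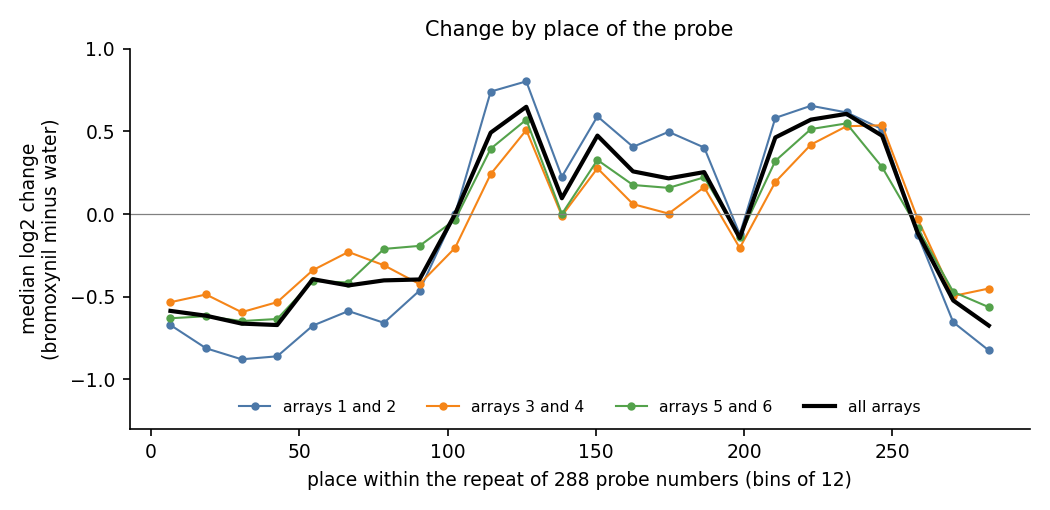
Median log2 change of bromoxynil minus water (y axis) by the place of the probe within the repeat of 288 probe numbers (x axis, bins of 12 places), for all arrays (black) and for each pair of consecutive arrays (colours). The profiles of the 3 pairs correlate at 0.938 to 0.973.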

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

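The tests of the place on the array, of the array numbers and of the shape of the intensity distribution were chosen only after those results were seen, except the counts over other splits and the place-adjusted shift of the median, which were set before their values were known. For the 99th percentile, the bound was set with its value already known, after the question of saturation had first been left open.

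Of 68 groups of 6 arrays examined, 4 had 1 array far from the others, and chance gives about 5% of groups. AT3G25680 was at log2 -0.25 on bromoxynil array 6, against 0.18 to 0.39 on the others. AT5G46390 was at -0.97 on bromoxynil array 2, against 0.46 to 1.01. AT2G30100 was at 1.62 on bromoxynil array 1, against 1.29 to 1.40. Water array 2 had 3.14% of its values at 0, against 3.58% to 3.81% on the others.

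The log2 change of a probe followed its number with a regular repeat, and the profile over places from odd repeats correlated with that from even repeats at a Spearman rho of 0.762 (permutation p = 1e-05, the smallest that 100000 shuffles can give), which is consistent with an effect of the place on the array. Different genes at neighbouring numbers would leave the repeats unrelated, and their profiles correlated at a median of 0.723. After the place adjustment 1126 of 1872 called probes stayed called in the same direction, against 1736 after removing shuffled places. The part of the place effect that the adjustment took out is therefore not the whole cause of the calls. The adjusted changes kept a rank autocorrelation of 0.148 at lag 288, against 0.380 before, so a remaining place effect cannot be excluded. The repeat was found in the difference between 2 pairs of water arrays. The differences between pairs of bromoxynil arrays, not used to find it, had their highest rank autocorrelation at the same lag of 288 (0.291 to 0.370). The repeat thus appeared within a group. Same-number arrays of the 2 groups deviated together, so the bromoxynil differences are not an independent check of the lag. Why the trend differs between the groups stays open, and an effect of bromoxynil was not tested apart from it on the other 746 probes, of which 737 lost the call and 9 were called with the sign turned.

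Arrays of the same number deviated together. The consecutive numbers 1 and 2, 3 and 4, and 5 and 6 within a group did so over probes above the dimmest 25% (mean correlation 0.412). Over all probes their mean correlation was 0.0855 (range -0.048 to 0.391). Deviations from the mean of the same 6 arrays correlate negatively on average when nothing is shared, so that value does not show that these pairs share nothing. Each same-number correlation between the groups lay above those with the neighbouring number, in 12 of 12 comparisons. Of 720 orderings of the numbers, 1 gave a mean as high (exact permutation p = 0.00139). This would be seen with 2 sets of spots on each of 3 filters that both groups shared. It shows only that a number was shared between the groups, and does not test how many filters or sets of spots there were. Plants or RNA shared by consecutive numbers are not the whole cause, since same-number correlations exceeded neighbouring-number ones by 0.285. Under the shared-filter hypothesis the 6 arrays of a group may hold 3 independent measurements, and averaging consecutive numbers called 1230 probes. The consensus correlation of consecutive pairs was 0.602, which argues against 6 independent arrays per group. The labels and the value over all probes do not settle how many independent measurements there were, and the design names no biological group for the numbers.

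The middle of the deposited distribution rose against the brightest features with bromoxynil, by 0.46 at the median (exact permutation p = 0.00216). A single scaling factor per array would move all percentiles alike, and the median moved 0.46 more than the 95th percentile. Background added to the bromoxynil arrays would raise the lowest values, and the 5th percentile shifted by -0.54. That percentile lies just above the zeros, a mean of 3.58% of values with water and 4.16% with bromoxynil. How background was subtracted is not known, so the 5th percentile cannot decide about added background. Saturation of the brightest spots on those arrays would bring the 99th percentile closer to the top, and it shifted by -0.32. The place adjustment reduced the shift of the median against the 95th percentile to 0.28, so the place may hold part of it. Because the adjustment left part of the repeat in the changes, this does not show that the place cannot hold the rest. A difference in background, labelling or exposure and an effect of bromoxynil on abundant transcripts stay open as untested.

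For the count of called probes, 1 of 100 splits of the 12 arrays, drawn from 462, gave as many as the real split's 1872, which was the real split, and the highest of the others gave 3. Among the 32 splits that part every same-number pair, 1 gave as many, again the real one, and the highest of the others gave 0. If the 12 arrays are independent, chance assignment of arrays to groups does not account for the count. The splits did not keep consecutive numbers together, so they cannot decide this if consecutive numbers share errors. They also do not exclude the place or another array effect that follows the groups. For gene lists, 100 of 100 splits gave at least the real count of 0, and the highest of the others gave 1. No split can give fewer than 0, so this comparison cannot decide anything about the lists.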

How the results depend on the processing

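The place adjustment, the block on averaged pairs and the random block were chosen only after the results were seen. The number of called probes stayed within 1.5 times of 1872 in 9 of 11 alternatives and with each array left out (1755 to 1890), and was 1230 with consecutive pairs averaged and 956 with the place adjustment, averaged pairs and the replicate block together. With the replicate block alone it was 2055, with the random block 1456 and with the place adjustment alone 1629, of which 1126 were shared in direction with the 1872. The share of higher calls was 67.0% on the deposited values, 37.7% with medians centred, 47.4% without the dimmest 25%, 42.1% with pairs averaged, with and without the block, and 47.5% with place, averaging and block together; leaving out an array gave 43.8% to 46.0%.

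The 1 single list tested, of plastid ribosomal proteins, did not pass camera in any alternative run and passed fry (1 list); without the dimmest 25% too few genes were left for a list test. The difference between photosynthesis and plastid gene expression median changes was -0.55, also with pairs averaged, with or without the block. Its call rests on the exact test of another measure, the per-array difference of list medians. That call was lost with pairs averaged (exact p = 0.3, the smallest possible being above 0.05) and with pairs averaged and blocked. The difference of median changes turned to 0.26 without the dimmest 25% and to 0.16 with the place adjustment, alone or with averaging and block. Without the dimmest 25% the per-array difference of list medians, which the exact test uses, stayed lower with bromoxynil, so these measures disagreed there. Leaving out an array gave differences of median changes of -0.77 to -0.18, and the exact test of the per-array difference lost the call in 9 of 12. The variance model and random block do not enter that test. The cause of these changes was not tested.

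Of 733 values of 32 named genes, 702 kept direction and call, 20 lost and 6 gained the call, and 5 reversed. AT1G29070 lost it with medians centred, pairs averaged (with or without block), the random block and both place-adjusted fits, and without water array 3, 4 or 6 or bromoxynil array 1, 2, 3 or 5, and PSB27 gained it without water array 2 (-1.06). The reversed values were PSBW at -0.21 with medians centred, PSAN at 0.15 with the place adjustment, alone or combined, and 0.020 without bromoxynil array 4 (range with each array left out -0.20 to 0.020), and AT5G65220 at -0.47 without that array (range -0.47 to 0.87), values set by the number put in for zeros and by 1 array of a group, which give no fold or direction. Of 460 values of the 20 largest changes, 458 were kept and 0 reversed; AT4G31930 lost the call with pairs averaged (adjusted p = 0.0616 in limma; range over alternatives 0.000551 to 0.0876) and with pairs averaged and blocked. The replicate block gained the call of PSB27 and changed no call of the other named genes.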

Other observations

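The gene groups in this part, their tests and the unnamed probes were chosen only after the results were seen. Of 5 cell wall enzymes, 4 fell, among them CSLA01 (AT4G16590), a mannan synthase, with a log2 change of -1.14 ± 0.15, and the endoglucanases GH9B8 (AT2G32990, -1.11 ± 0.24) and GH9B16 (AT4G38990, -0.88 ± 0.09). The group had a camera p of 0.0105, an adjusted p of 0.0843 over 8 groups and an adjusted p of 0.207 with an estimated correlation. After the place adjustment its camera p was 0.165, with an adjusted p of 0.659. Of 6 redox and detoxification genes, 4 fell, including GLDH (AT3G47930), which makes vitamin C in its last step, with a log2 change of -1.42 ± 0.07, and CHL (AT3G47860), a plastid lipocalin, at -0.81 ± 0.19. That group had a camera adjusted p of 0.209, and it was drawn up without the peroxiredoxin AT3G52960, which rose by 2.46. After the place adjustment 2 of the cell wall enzymes still fell, CSLA01 and GH9B16, at -0.66 and -0.33, while GH9B8 had a change of -0.54 that did not pass. Of the redox genes, 2 still fell then, GLDH and CHL, at -0.82 and -0.74, and GLX2-1 (AT2G43430), a glyoxalase, rose by 0.83. With averaging and block added to the place adjustment, GH9B16 and GLX2-1 no longer passed, with log2 changes unchanged at -0.33 and 0.83. Whether the lost calls reflect low power was not tested. The 0% of simulated changes of 1 recovered with a block does not settle it, since those errors were not shared between groups.

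Among 10 proteins of the photosystems, the NDH complex and the cytochrome complex, 2 rose and 3 fell. NdhS (AT4G23890), a subunit of the NDH complex of cyclic electron flow, rose by 1.28 ± 0.33, and by 1.63 after the place adjustment, but did not pass with consecutive arrays averaged alone. LPA19 (AT1G05385), an assembly factor of photosystem II, had a log2 change of -1.12 ± 0.11, and of -0.33 after the place adjustment, where it did not pass once averaging and block were added. AT5G58330, the plastid NADP-dependent malate dehydrogenase that exports reducing power, rose by 1.53 ± 0.29, and by 1.48 after the place adjustment, while PRK fell. None of 5 tetrapyrrole and pigment synthesis genes passed the test, and 2 did after the place adjustment, Z-ISO (AT1G10830), from 0.09 ± 0.14 to 0.64, and HEMA3 (AT2G31250), from -0.21 ± 0.14 to 0.40, but not with averaging and block added. Of 8 transcription regulators of development, 2 rose and 3 fell, with a camera adjusted p of 0.924. After the place adjustment 2 rose and 0 fell, and 0 rose or fell with averaging and block added. Whether the probes detect the genes they are annotated with was not tested.

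Unnamed probes above the dimmest 25% were among those with large changes in each direction. Probe 2188 rose by 3.41 ± 0.16 on the log2 scale, 10.6-fold, from a deposited intensity of 1.18 ± 0.28 (SD, n = 6) to 11.9 ± 1.58, and by 3.07 after the place adjustment. Probe 3010 rose by 2.98 ± 0.17. Probe 333 and probe 3466 fell, with log2 changes of -2.40 ± 0.11 and -2.38 ± 0.14. After the place adjustment the changes were 2.59 for probe 3010, -1.64 for probe 333 and -1.79 for probe 3466.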
